A study of Homo sapiens with 2 samples.

How the data were processed

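Gene expression was measured on Affymetrix 3' expression arrays in GFP-SAS cells, a human squamous carcinoma line of the tongue. Per the labels' protocols, cells received 25 nM of an LNA/DNA antisense oligonucleotide for 24 h, directed either against miR-361-3p or against no target, and 10 ng of total RNA was labelled with biotin. There was 1 array per group. No replicate error could be computed, and no p-value is given.

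The deposited values are log2 expression values per probe set, which the authors made with RMA, per the submitters' processing notes. RMA corrects background, makes the distributions of arrays alike and summarises the probes of a set. Its version, the software and the arrays normalized together are not given in the sources used here. The sorted values of the arrays differed by at most 0.11, so their distributions were close and not identical. The median was 4.64 on the anti-miR array and 4.63 on the control array, and the values ranged from 1.99 to 13.3 and from 1.94 to 13.4. No detection call came with the values, and the number of arrays limits the precision.

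The table held 49386 probe sets, of which 93 were array controls and were left out of gene values. The platform annotation used here paired 45259 probe sets with 1 gene symbol and 1327 with several, and left 2800 unnamed. Of the 45253 probe sets with 1 symbol that were not controls, 45172 matched the RefSeq gene table of GRCh38.p14 by Entrez ID, and their symbols were taken from it. The files name no genome build, so no coordinates are given. Gene length, the genomic span of a gene in that table, was used only as a property of the gene.

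A probe set was retained if it reached the array's median on at least 1 array. A gene's value was the mean over its retained probe sets, which gave 24127 probe sets and 11272 genes. Differences are the anti-miR value minus the control value on the log2 scale. The spread between probe sets of a gene is given as a within-array technical error. Such probe sets can share probes, and this error holds no variation between cultures. Pooled over 6263 genes with at least 2 retained probe sets, its SD was 0.29. Genes were counted as higher or lower at a threshold of 1.5-fold.

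37 gene lists were fixed before the data were examined. Older symbols were updated through the RefSeq table. A list's median difference was placed among those of 10000 random lists of the same size, drawn from 20 bins of mean expression. A list at or beyond the 2.5th or 97.5th percentile is called outside the random range. The percentile describes these 2 arrays and is not a test across cultures. A listed gene is called measured if it had at least 1 retained probe set, so genes that are not measured can have dim probe sets on the array. Lists with fewer than 5 measured genes got values only. In simulated data on 11272 genes with an SD of 0.3, 184 of 200 genes changed by 2-fold passed the threshold, as did 574 unchanged genes. Of 200 simulated lists of 16 genes without a shift 9 lay outside the random range, and all 100 lists shifted by 0.5 lay above it. The simulated differences were independent and had no trend with gene length, while the measured differences had an SD of 0.58. The simulation thus does not show how the percentiles behave in these data.

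The genes named were chosen by a rule fixed before the data were examined. It took the 12 largest increases and the 12 largest decreases among genes whose retained probe sets all differed in one direction. It added up to 4 members with the largest absolute difference from each list outside the random range and from the p53, cell cycle, interferon and differentiation lists. OSR2, SH2B1 and DUSP2, linked to miR-361-3p in publications as remembered, and the array control genes GAPDH and ACTB were named in any case. CHM, whose intron holds the miR-361 hairpin, was on the rule's list and is not analysed here. A planned comparison of genes with a miR-361-3p seed site in the 3' UTR needs transcript sequences, which were not used here.

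The alternatives were no filter, a filter at the 75th percentile, the probe set with the highest level or the median of probe sets as the gene value, centring on the median or on a lowess trend (fraction 0.3), a 2-fold threshold, and plain _at probe sets alone. Matching on gene length as well, with 10 bins each of expression and length, and a restriction to genes with agreeing probe sets were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.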

Results

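The study compared GFP-SAS cells treated with an inhibitor of miR-361-3p with cells given a non-target oligonucleotide, to find genes that respond to loss of this microRNA. SAS is an established line of tongue squamous cell carcinoma, and GFP-SAS carries green fluorescent protein. LNA/DNA oligonucleotides are short antisense strands in which locked nucleotides strengthen pairing with the target RNA. Both groups received 25 nM for 24 h, and each was measured on 1 array. The log2 values of the arrays correlated with Pearson's r = 0.974 across all 49386 probe sets, which are not independent replicates.

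The hybridization controls, bacterial transcripts added after labelling, differed between the arrays by 0.09 ± 0.10 (SD over 9 probe sets). The poly-A controls, added to the RNA before labelling, were higher on the anti-miR array by 0.32 ± 0.19 (SD over 12 probe sets). GAPDH, a glycolytic enzyme used as an array control, differed by -0.0047 on the log2 scale (12.57 on both arrays, 1 probe set). ACTB, cytoplasmic actin, differed by -0.13 ± 0.01 (SD over 3 probe sets). The 3' minus 5' control probe sets differed between the arrays by 0.03 for GAPDH and 0.04 for ACTB.

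Of 11272 genes, 928 were at least 1.5-fold higher on the anti-miR array and 1602 were at least 1.5-fold lower. At 2-fold, 139 genes were higher and 787 lower, and at 4-fold 3 were higher and 101 lower. The median gene differed by 0.13, with quartiles of -0.21 and 0.33. Higher genes made up 36.7% of the genes past 1.5-fold, and 20.4% (499 higher, 1951 lower) once this median was subtracted. Of the genes with at least 2 retained probe sets, all probe sets differed in one direction in 457 of 459 higher genes and in 1060 of 1103 lower genes. These genes were selected on the mean of the same probe sets, so this agreement is no separate evidence for the calls. Without replicates, none of these differences can be set against variation between cultures.

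**Figure D1:**
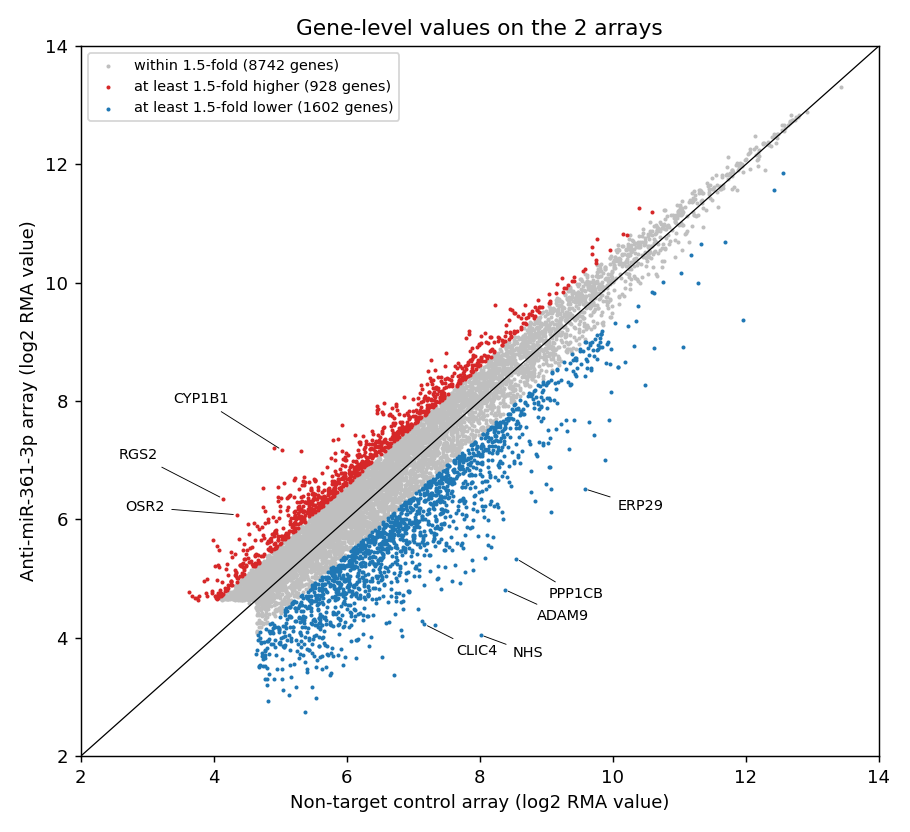
Each point is 1 of 11272 genes, with its log2 RMA value on the control array (x axis) and on the anti-miR array (y axis), and the line marks equal values. Red points are the 928 genes at least 1.5-fold higher and blue points the 1602 genes at least 1.5-fold lower on the anti-miR array; the lower genes reach farther from the line.

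OSR2, a zinc finger transcription factor of the odd-skipped family, ranked 6 of 11272 genes by increase. It was 3.32-fold higher on the anti-miR array, with a log2 difference of 1.73 ± 0.12 (SD over 4 probe sets) and values of 6.08 against 4.35. The probe sets ranged from 3.03-fold to 3.62-fold. Its control value lay below that array's median of 4.63 and is not shown to be above background, so the fold and the rank are not exact sizes. The study may have picked OSR2 from these arrays, so its rank is not independent evidence. SH2B1, a signalling adaptor, differed by 0.12 ± 0.07 (SD over 5 probe sets), close to the median gene. DUSP2, a phosphatase of MAP kinases, differed by 0.41 (1 probe set).

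The largest increase was at the probe set assigned to SNORA65, a small nucleolar RNA encoded within another gene, at 4.93-fold (1 probe set). Whether this probe set reads the small RNA or a transcript of the host gene was not tested. RGS2, a regulator of G protein signalling, was 4.63-fold higher (1 probe set). CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor, was 4.43-fold higher, with a log2 difference of 2.15 ± 0.22 (SD over 3 probe sets). The zinc finger genes ZNF227 and ZNF441 were 3.57-fold and 3.00-fold higher (1 probe set each). RASSF1, which includes a tumour suppressor isoform, was 3.20-fold higher (log2 difference 1.68 ± 0.21, SD over 2 probe sets). CALML4 was 3.49-fold, THAP2 3.17-fold, CDADC1 2.95-fold and NECTIN4, a cell adhesion molecule, 2.85-fold higher. RRP7A was 2.93-fold higher on average, but its 5 probe sets ranged from 1.38-fold to 5.78-fold. On the control array the gene values of all 12 largest increases, from THAP2 (3.99) to RASSF1 (5.92), lay within the range of the nonspecific control probe sets, which reached 6.87. This upper end is the highest of 23 such probe sets. The 75th percentile of all probe sets on that array was 6.62, so most probe sets lay below it. A position within the range is therefore common and not particular to the genes named here and below. RGS2 (4.14), THAP2, NECTIN4 (4.05) and OSR2 also lay below the median. Only 1 probe set, of RRP7A (6.96), was above that range, and it differed by 0.46, short of 1.5-fold. The other probe sets of RRP7A and the other 11 genes are not shown to be above background there. The folds and ranks of all 12 are therefore not exact sizes.

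The decreases were larger. NHS was 15.6-fold lower on the anti-miR array (4.05 against 8.01, 1 probe set). ADAM9, a membrane-bound metalloprotease, was 11.8-fold lower, with a log2 difference of -3.56 ± 0.82 (SD over 4 probe sets). MOB1B, a Hippo pathway adaptor, was 10.2-fold lower (1 probe set). PPP1CB, a catalytic subunit of protein phosphatase 1, was 9.25-fold lower (-3.21 ± 0.94, SD over 4 probe sets). MIPEP, a mitochondrial peptidase, was 8.64-fold lower (1 probe set). ERP29, a chaperone of the endoplasmic reticulum, was 8.33-fold lower (-3.06 ± 0.48, SD over 4 probe sets). GRHPR, a glyoxylate reductase, was 7.68-fold and ACTR3, a subunit of the Arp2/3 complex, 7.40-fold lower (2 probe sets each). UBE2E2 was 7.30-fold, IL1RAPL1 7.19-fold and FAM169A 6.98-fold lower. CLIC4 was 7.64-fold lower on average, with probe sets at -4.83 and -1.04. On the anti-miR array NHS (4.05), MOB1B (3.37), MIPEP (4.22), UBE2E2 (3.67), IL1RAPL1 (4.28), FAM169A (4.02) and CLIC4 (4.23) lay below the array's median of 4.64, as did 2 probe sets each of ADAM9 (3.99 and 3.76) and PPP1CB (4.62 and 4.45). The gene values of all 12 largest decreases lay within the range of the nonspecific control probe sets, which reached 7.16. Most probe sets on that array lay below this upper end too, as their 75th percentile was 6.53. Only 1 probe set each of ACTR3 (7.70) and ERP29 (7.52) was above that range, so the other 10 genes are not shown to be above background there, and their folds and ranks are not exact sizes. With dim probe sets kept in the gene mean, NHS differed by -2.53, MOB1B by -1.68, PPP1CB by -2.23 and CLIC4 by -2.18, and of the higher genes CYP1B1 by 1.54, RASSF1 by 1.13, CDADC1 by 0.91, CALML4 by 0.78 and NECTIN4 by 0.64, all still past 1.5-fold.

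**Figure D2:**
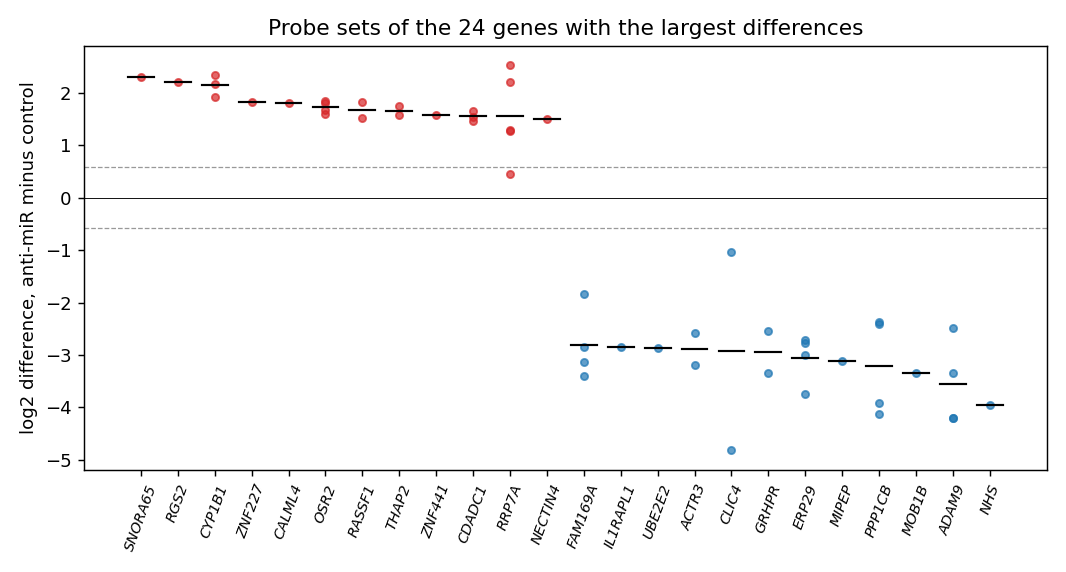
Each dot is the log2 difference (y axis, anti-miR minus control) of 1 retained probe set of the 24 genes with the largest increases (red) and decreases (blue); black bars are gene means and dashed lines mark 1.5-fold. Probe sets of OSR2 lie between 1.60 and 1.85, while those of CLIC4 lie at -4.83 and -1.04.

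Of 37 gene lists, 35 had at least 5 measured genes, and 6 of these lay outside the random range, 4 below and 2 above. If list members varied independently and without a trend with gene length, 1.75 of 35 lists would be outside by chance. Members of a list can vary together, some lists share genes, and differences followed gene length. The count of 6 is therefore not a test against 1.75. With length matched as well, 3 of the 6 stayed outside. The microRNA biogenesis and silencing list had the lowest median, -0.47 (percentile 0.19). Of its 17 measured genes 7 were at least 1.5-fold lower and 1 was higher. XRN1, an exonuclease, was 3.38-fold lower, TUT4, a uridylyltransferase, 2.40-fold and AGO4, an Argonaute protein, 2.26-fold. TNRC6A, a partner of Argonaute, differed by -1.32 ± 0.17 (SD over 4 probe sets). With no filter on dim probe sets AGO4 differed by -0.22, short of the threshold, XRN1 by -0.88 and TNRC6A by -0.94. On the anti-miR array AGO4 (3.51), XRN1 (5.70 and 5.55) and TUT4 (4.71 and 5.79) lay within the range of the nonspecific control probe sets. They are not shown to be above background there, so their folds are not exact sizes. The highest probe set of TNRC6A, at 7.90, lay above that range. These genes are long, with a list median of 71.8 kb, and among lists matched also on gene length the list lay at percentile 4.14, inside the random range.

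The epithelial junction list had a median of -0.20 (percentile 1.03), with 4 of 18 genes lower and 1 higher. ESRP1, an epithelial splicing regulator, was 2.17-fold lower. The tight junction genes CLDN1 and TJP1 were 1.88-fold lower each, with the probe sets of TJP1 at -1.37 and -0.45. PKP1, a desmosomal plakophilin, was 1.79-fold higher. The control value of PKP1, 4.22, is not shown to be above background, and with no filter it differed by 0.44, short of the threshold. The list lay at percentile 0.46 with length matched.

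Immediate early genes had a median of -0.15 (percentile 1.37), with 3 of 23 genes lower and 0 higher by 1.5-fold. DUSP5 and DUSP6, phosphatases induced by ERK signalling, were 2.19-fold and 2.05-fold lower, and KLF6, a transcription factor, was 2.15-fold lower (-1.11, and -0.70 with no filter). The KLF6 probe sets on the anti-miR array, from 4.66 to 7.09, lay within the range of the nonspecific control probe sets. The fold of KLF6 is therefore not an exact size. IER2 differed by 0.56 in the other direction. With length matched, the list lay below all 10000 random lists. The random range of these lists of similarly short genes was 0.13 to 0.39, so part of the distance from it is their rise.

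The list of YAP/TAZ targets had a median of -0.24 (percentile 1.81), with 4 of 11 genes lower and 0 higher. That median was the value of TGFB2, whose level on the anti-miR array, 4.56, is not shown to be above background. The highest member was GADD45B at 0.57, short of the threshold. Of the 15 listed genes, CCN2 and ANKRD1 were among those left out by the filter on dim probe sets. With no filter all 15 had values, and the list median was -0.225 (percentile 0.17). CCN1, a matricellular protein, was 1.80-fold lower (-0.85 ± 0.09, SD over 2 probe sets). AJUBA was 2.12-fold lower, with probe sets from -1.85 to -0.69, and CRIM1 1.82-fold lower, with probe sets at -1.56 and -0.16. AXL, a receptor tyrosine kinase, was 2.86-fold lower on average, with probe sets at -2.86 and -0.18. Both lay within the range of the nonspecific control probe sets on the anti-miR array (7.15 and 6.28), so the fold of AXL is not an exact size. The list lay at percentile 0.71 with length matched.

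The p53 target list had a median of 0.30 (percentile 98.1), with 4 of 20 genes higher and 1 lower. SESN1, GADD45A and CCNG1, which act in stress and cell cycle control, were 2.06-fold, 1.75-fold and 1.66-fold higher. FAS, a death receptor, was 1.81-fold lower. The other 15 genes lay within 1.5-fold, among them CDKN1A (0.03) and MDM2 (-0.23), which were named after their values were seen. SESN1 on the control array (4.75 and 5.75) and FAS on the anti-miR array (5.80 and 6.22) lay within the range of the nonspecific control probe sets. The folds of these genes are therefore not exact sizes. The autophagy and lysosome list had a median of 0.32 (percentile 97.9), with 4 of 18 genes higher and 3 lower. NEU1, a lysosomal sialidase, was 1.86-fold and ATG12 1.77-fold higher, while LAMP1 was 2.16-fold and ATG5 1.84-fold lower. With length matched, the lists lay at percentiles 92.7 and 92.4, inside the random range.

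Cell cycle lists stayed inside the random range. The G1/S and DNA replication list had a median of 0.15, with 1 of 23 genes higher and 3 lower. CDT1, a licensing factor, was 1.73-fold higher, POLA1 1.94-fold and GINS1 1.58-fold lower, and MCM4 was 2.39-fold lower with probe sets from -2.35 to -0.27. POLA1 on the anti-miR array (6.64, 1 probe set) lay within the range of the nonspecific control probe sets, so its fold is not an exact size. The G2/M and mitosis list had a median of 0.18, with 4 of 23 genes higher and 4 lower. The mitotic kinesins KIF20A and KIF23 were 2.02-fold and 1.80-fold higher, AURKB, a mitotic kinase, 1.75-fold higher, and BUB1B, a checkpoint kinase, 1.73-fold lower.

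Interferon-stimulated genes had a median of 0.18, inside the random range. IRF9 was 1.61-fold higher, with probe sets from 0.17 to 1.10. It was the single gene past 1.5-fold of 13 measured and 24 listed. ISG15 differed by 0.54, IFI6 by 0.51 and RIGI by -0.50. On the control array IRF9 (4.23 to 5.47), ISG15 (6.06) and IFI6 (5.19) lay within the range of the nonspecific control probe sets. RIGI (4.43 to 4.49) did so on the anti-miR array, so none of these differences is an exact size. Of 26 listed keratinocyte differentiation genes 9 were measured. Among these KRT10, a suprabasal keratin, was 1.60-fold higher, SPRR1A differed by 0.44, KLK7 by 0.32 and CALML3 by -0.30. SPRR1A and KLK7 on the control array (4.39 and 5.30) and CALML3 on the anti-miR array (5.47) lay within the nonspecific range as well. Of the markers of other cell types, 6 endothelial genes had a median of 0.09 and 6 skeletal muscle genes a median of 0.31, both inside the random range. The 4 measured leukocyte genes had a median of 0.16, and COL6A3, the 1 measured fibroblast gene, differed by -0.46.

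**Figure D3:**
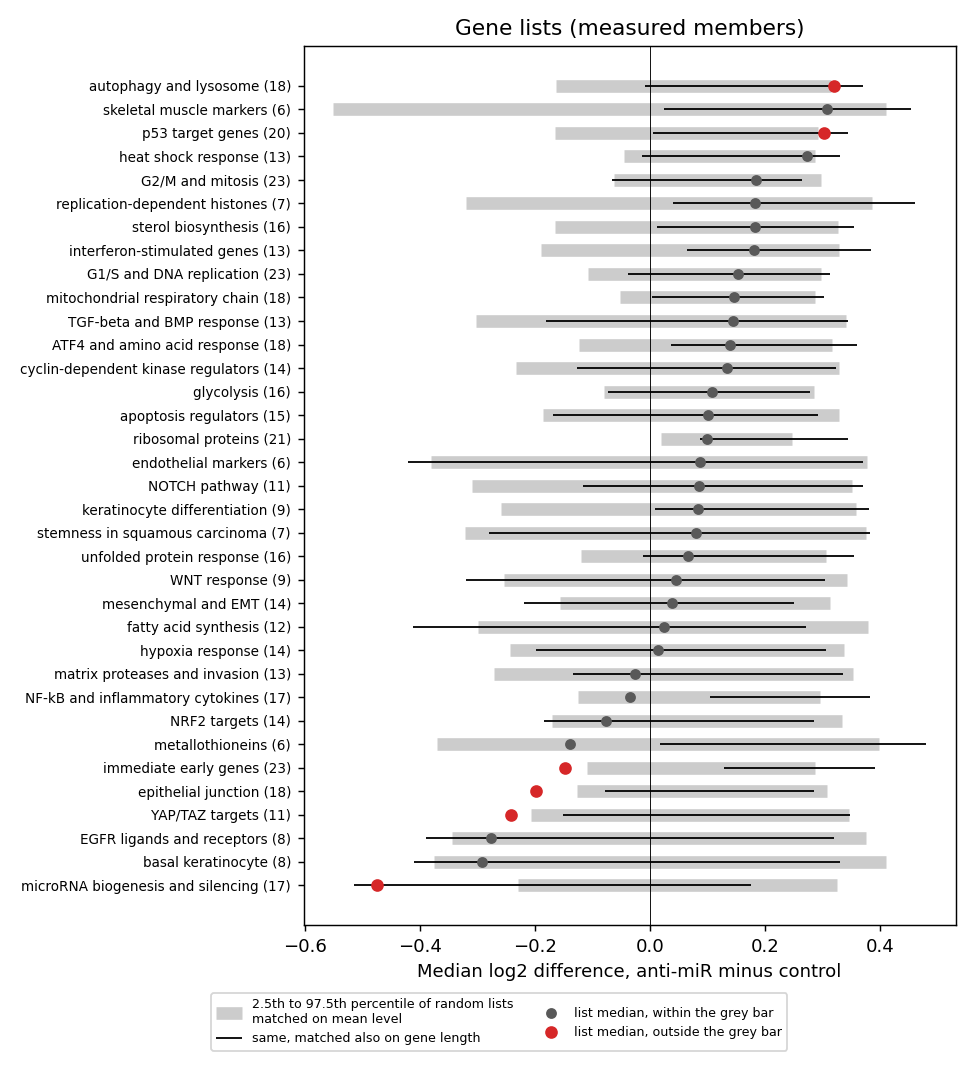
Dots are the median log2 difference (x axis, anti-miR minus control) of each of 35 gene lists, with the number of measured genes in parentheses; grey bars span the random range from 10000 lists matched on mean level, and black lines the same with gene length matched as well. The 6 red dots lie outside the grey bars, and the dot of the microRNA biogenesis and silencing list lies inside its black line.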

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

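Signals above their level on the control array were also found in data outside the gene comparison. Of 1264 retained probe sets for which no gene is listed here, 5 were at least 2-fold higher on the anti-miR array, but more of them, 105, were at least 2-fold lower. The nonspecific control probe sets of GC class 15 and above were higher by a median of 0.23 over 11 probe sets, while those below this class differed by a median of -0.0038. The poly-A spike control probe sets were higher by a mean of 0.32 over 12 probe sets. That rise was close to the upper quartile of the gene differences, 0.33. It was also close to the medians of the p53 list (0.30), the autophagy list (0.32) and the ZNF genes (0.33). Taken alone, a gene difference of this size cannot be told apart from an offset between the labelling reactions. An offset shared by all genes would also move the random lists matched on mean level. Their medians were 0.11 for the p53 list, 0.12 for the autophagy list and 0.13 for the ZNF genes. The percentiles are relative to such a shared offset, while an offset limited to some genes is not excluded.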

How the results depend on the processing

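With 1 array per group, no array could be left out, and depth here means signal over background, for which no detection call was available. No paired analysis was possible because each group holds 1 sample. The seed-site comparison and its alternatives were not run, since they need transcript sequences. Against 928 genes higher and 1602 lower, centring on the median gave 499 higher and a lowess trend 547 higher; both move the threshold relative to the median gene. A 2-fold threshold gave 139 higher and 787 lower. Plain _at probe sets alone gave 318 higher and 507 lower among 3438 genes, and genes with 2 or more agreeing probe sets, an alternative added after seeing the data, 457 higher and 1060 lower among 4954; fewer genes were tested in both. The other alternatives kept both counts within 1.5 times. The number of lists outside the random range was 5 to 7 under the other settings and 0 with plain _at probe sets, where 11 lists could be computed. Of the 24 genes with the largest differences, 8 were measured and past 1.5-fold in their direction with plain _at probe sets. The p53 list was inside the random range with no filter (percentile 95.3) and with a lowess trend (97.2), and the autophagy list with the stricter filter (94.98) and with the probe set of highest level (95.03). The EGFR ligand and receptor list, inside the range at percentile 3.98, was outside it with the stricter filter (1.16) and the probe set of highest level (1.71), and the heat shock list with the stricter filter (99.3). None of these list or gene values reversed.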

Other observations

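The tests on RNA degradation, zinc finger genes, ERK-responsive genes and differences between cultures, the gene families and all matching on gene length were chosen after seeing the data or part of them. Among 11 families picked by symbol, 286 zinc finger genes named ZNF had a median of 0.33, with 72 at least 1.5-fold higher and 12 lower. The 9 measured SNHG genes, hosts of small nucleolar RNAs, had a median of 0.57, with 4 higher and 2 lower. The 25 UBE2 genes, ubiquitin-conjugating enzymes, had a median of -0.46, with 9 lower and 1 higher, and lay below all 10000 random lists even with gene length matched. The 38 USP genes, ubiquitin-specific proteases, had a median of -0.35 (percentile 2.47 with length matched). The other 7 families lay inside the random range with length matched: MRPL and MRPS at percentile 93.8, PSM at 88.0, ARHGAP and ARHGEF at 82.3, POLR at 96.5, SRSF at 33.6, DOCK at 42.2, and ITGA and ITGB at 28.6. Matched on mean level alone, 3 of these 7 lay outside it: MRPL and MRPS (99.93), POLR (99.2) and DOCK (0.91). Of the lists inside the random range, 2 left it with length matched: the NF-kB and inflammatory cytokine list (median -0.04, percentile 0.04) and the metallothioneins (median -0.14, percentile 0.23). Random lists of similarly short genes were higher, with ranges of 0.10 to 0.38 and 0.02 to 0.48. These low percentiles thus mean that the lists lacked that rise, more than that they fell. In the NF-kB list, 2 of 17 genes were at least 1.5-fold higher, 2 lower and 13 within. The genes past 1.5-fold were named after their values were seen. The feedback inhibitors TNFAIP3 and NFKBIA differed by 0.77 and 0.67, and the cytokines CXCL8 and IL1A by -1.24 and -0.93, with CXCL8 at 4.36 on the anti-miR array, not shown to be above background.

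Genes with long genomic spans were lower on the anti-miR array. Of 2579 genes under 10 kb, 49 were at least 1.5-fold lower and 325 higher, while of 1507 genes of 100 to 300 kb 715 were lower and 14 higher. Spearman's rho between length and difference was -0.49 across 11266 genes, which are not independent replicates, and lay between -0.58 and -0.38 under 6 other settings. The gap in medians between genes over 100 kb and under 10 kb was taken in 5 equal groups of genes by mean level. It was -0.48 or lower in each, which argues against expression level. Among the 2817 genes with the highest level it was -0.90, which argues against background. The 3' minus 5' controls differed by at most 0.040, which argues against RNA degradation only for GAPDH and ACTB, the 2 transcripts tested. The measured falls were not of equal size, as the interquartile range of genes over 100 kb was 3.03 times that of genes under 10 kb. Long genes were dimmer, with a median level of 5.83 at 100 to 300 kb and 5.33 over 300 kb, against 6.26 under 10 kb. Differences near background are not exact sizes, so a fall of equal true size is not excluded. Loss of long precursor RNAs, for example through oligonucleotide pairing within introns, or reduced elongation may account for the lower long genes and was not tested. With 1 array per group, a difference between the 2 cultures, extractions or labelling reactions apart from the oligonucleotide cannot be told apart from the treatment.

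Gene length may account for the low microRNA biogenesis and silencing list, which lay at percentile 4.14 once length was matched. Some short genes were nevertheless among the 101 genes lower by at least 4-fold: 11 of these were under 30 kb. H2AZ1, a histone variant with a span of 2.19 kb, differed by -2.58 ± 0.14 (SD over 4 probe sets). In 11 of 6263 genes with at least 2 probe sets, probe sets passed 1.5-fold in both directions, among them DMXL1, with probe sets from -2.54 to 0.93.

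The higher zinc finger genes were not accounted for by length, since their median lay above all 10000 random lists matched on it (percentile 100). Without _x_at and _s_at probe sets it lay above all lists matched on mean level alone (percentile 100), which argues against cross-hybridization. The 76 ZNF genes above the median level had a median of 0.33, at percentile 99.99 of lists matched on mean level alone. This does not exclude background. The median levels of the length classes, from 5.33 to 6.38, lay within the range of the nonspecific control probe sets. Genes above the median level can therefore lie within that range too. A difference between the 2 cultures, extractions or labelling reactions apart from the oligonucleotide stays open here too, with 1 array per group, so the pattern may not come from the treatment.

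The lower immediate early genes may reflect lower output of the ERK pathway. Of 13 other ERK-responsive genes, none shared with that list, 11 were measured. Their median was -0.34, at percentile 0.14 of lists matched on level and length, with 4 lower and 0 higher by 1.5-fold. The lower genes included the longest members, SPRED2 (125.4 kb), SPRED1 (104.4 kb) and ETV5 (62.8 kb). The other was UPP1, at -0.64 ± 0.71 (SD over 2 probe sets). Among all genes, 47.4% of those of 100 to 300 kb and 15.7% of those of 30 to 100 kb were lower. The count of lower members may therefore follow gene length, for which only the percentile was matched. The members were uneven. ETV5 was the lowest at -2.35 ± 0.99 (SD over 4 probe sets), with an anti-miR value of 4.02 that is not shown to be above background, while ETV4 differed by -0.10, SPRY1 by -0.07, MAFF by 0.22 and PLAUR by 0.27. In the immediate early list the ERK-induced genes SPRY2, SPRY4 and DUSP4 differed by -0.09, -0.09 and -0.10. The list median is consistent with the hypothesis in these 2 arrays, these members give it little support, and signalling itself was not measured.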
